A study of Mus musculus with 8 samples.

How the data were processed

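RNA was measured by sequencing in mucosal-associated invariant T (MAIT) cells sorted from mouse lungs. MAIT cells are innate-like T cells whose semi-invariant receptor recognises microbial vitamin B metabolites presented by MR1. Per the labels, RNA was isolated with the Qiagen RNeasy Plus Micro kit, libraries were made with the NEBNext Ultra II RNA kit, and sequencing was on a NextSeq500. The labels give every library the same floxed Bcl11b strain with a Plzf-driven Cre and state the genotype (wild type or knockout) separately, so how the wild-type animals differ from the knockout animals is not stated in the sources used here. They do not say whether the replicates of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

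The deposited values are read counts per gene symbol, as whole numbers that were not normalized. HISAT2, HTSeq, DESeq2 and the mouse build mm10 are named per the submitters' processing notes, without versions, roles or order. The annotation, the strand setting and the rule for reads that map to several places are not given in the sources used here. Counts of near-identical or overlapping genes are therefore uncertain. Among the genes reported these include Hspa1a, Mrgpra2a and Mrgpra2b, Lyz1 and Lyz2, Apol7b, the Gbp genes and the H2 genes. The table held 24449 symbols, of which 3090 had 0 counts in every library and 23375 were in the RefSeq annotation of GRCm38.p6, the assembly that mm10 also represents. That annotation supplied the coordinates and gene types. The table had no mitochondrially encoded gene: 0 of the 13 fixed as a quality list were present.

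The 8 libraries fell into 4 groups of 2 by state (steady state or Salmonella infection) and genotype, taken from the labels. Totals ranged from 1256020 to 5865968 counts. A gene at 0 counts in a library allows up to 3 counts, which corresponds to 0.511 to 2.39 CPM over the libraries. Intervals and these floors cover counting error only, since reads without molecular identifiers are not independent molecules.

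The main test was the quasi-likelihood (QL) F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter by group, a group means model over all 8 libraries, robust estimation and 4 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 over the 13405 genes tested was the threshold. The common dispersion was 0.0871, a biological coefficient of variation of 29.5%. Comparisons were knockout against wild type in each state, infection against steady state in each genotype, and the interaction of both. CPM values are TMM-scaled, with mean ± SD over n = 2 libraries. Log2 fold changes are given with their standard error (SE). Levels are relative to all counts of a library, so a change in the mixture of cells changes them.

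Before the data were examined, 34 gene lists were fixed, 19 of cell programmes and 15 of other cell types' markers and RNA quality genes. Of these, 31 had enough tested members for a set test. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance to one side, were run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. A rule fixed at the same time set the genes named. It took Bcl11b, then per comparison the 8 largest rises and 8 largest falls among called genes with at least 10 CPM in the higher group and no overlap between libraries, leaving out predicted genes, pseudogenes by name and receptor segments. It added per list up to 4 called members with the smallest adjusted p, or 2 members as values where none was called, the 3 smallest interaction p-values where none passed, and 10 genes called in both states. Some genes that the rule took are not reported here. Other genes are said to be chosen after their values were seen.

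Genes with 0 counts in the lower group are given as at least N-fold against 3 counts over that group, and genes with 1 to 3 counts as a ratio with a 95% counting interval. Alternatives planned before the data were examined were relative log expression factors, DESeq2 1.42.0, limma-voom, no low count filter, a stricter filter of at least 5 CPM on average, only the 4 libraries of a comparison, the replicate number as a block, and each library left out in turn. Added after the data were seen were the removal of the ribosomal RNA precursor row (Rn45s), the removal of both libraries with high Xist counts, and scaling to T cell genes. With a library left out, its partner was assumed to vary like the other groups. The removal of both libraries with high Xist left 1 library in each KO group. The spread in that fit came from the WT pairs, so it did not measure the spread between KO libraries.

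The main test was tested on simulated counts with 200 changed genes per comparison. For knockout against wild type at steady state (13067 genes) it recovered 38% of 4-fold and 2% of 2-fold changes, with 0 false calls. For the infected comparison (13001 genes) it recovered 46% and 2%, with 2 false calls. For infection in wild-type cells (13005 genes) the shares were 37% and 1%, with 2 false calls, and in knockout cells (13014 genes) 43% and 3%, with 1 false call. A simulated list of 25 genes changed by 1.5-fold was found in its direction, and 2% of 200 unchanged lists passed. Simulated genes varied independently, so this share cannot speak for lists of correlated genes. Each gene had the same dispersion in all groups, whereas measured replicates differed more in knockout than in wild-type groups. False calls in the measured data may therefore differ from those simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.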

Results

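Gene expression was measured by RNA sequencing in MAIT cells sorted from mouse lungs, in libraries labelled wild type (WT) or knockout (KO) for Bcl11b, a zinc finger transcription factor needed for T cell lineage commitment. WT and KO stand for these labels throughout, and WT or KO cells for the whole libraries, which also held markers of other cells. Cells came from uninfected lungs (steady state) and from lungs of animals infected with Salmonella, a bacterium that makes the vitamin B metabolites seen by MAIT cells. Each of the 4 groups had n = 2 libraries. Total counts were 2689741 and 2277728 in steady-state WT, 1256020 and 3659643 in steady-state KO, 2345238 and 2864218 in infected WT, and 5865968 and 4080602 in infected KO libraries. Between 16092 and 18008 genes had at least 1 count in a library, and 13405 genes were tested. The first principal component took 49.4% of the variance and the second 25.3%.

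Bcl11b itself had a lower mean in the KO libraries of both states, and the difference passed the test in infection only. The gene lies on the minus strand of chromosome 12 (107910403 to 108003602, GRCm38) and has 4 annotated exons. Its counts were 538 and 667 in steady-state WT, 28 and 273 in steady-state KO, 1191 and 1605 in infected WT, and 124 and 199 in infected KO libraries. The labels do not say which part was floxed, so whole-gene counts can include transcripts that lack it, and residual counts do not measure functional transcript. At steady state Bcl11b was at 254 ± 68.8 CPM (SD, n = 2) in WT and 40.7 ± 27.7 in KO cells, a log2 fold change of -2.59 ± 0.60 (SE) that did not pass the edgeR test (adjusted p = 0.0885). In infection it fell from 587 ± 32.5 to 37.1 ± 24.5 CPM (log2 fold change -3.99 ± 0.63, adjusted p = 0.0146). Per CD3 count, the T cell reference described next, Bcl11b differed by 0.64 ± 0.37 (SE) at steady state and by -1.20 ± 0.37 in infection, so it was not lower in steady-state KO libraries on that scale. Over the alternatives the steady-state adjusted p ranged from 6.47e-12 to 0.401, and it passed with DESeq2 (0.000503), with no low count filter (6.47e-12), with the replicate number as a block (0.0267), without infected KO replicate 1 (0.0279), without infected KO replicate 2 (0.0291) and without both libraries with high Xist (0.00145). The infected call was lost without infected WT replicate 1 (adjusted p = 0.0621) or 2 (0.107), over a range of 4.77e-25 to 0.107. The fit without both libraries with high Xist held 1 library in each KO group and did not measure the KO spread, so its pass is no further support. Between states, Bcl11b differed by 1.21 ± 0.56 in WT (adjusted p = 0.314) and by -0.20 in KO cells (adjusted p = 0.886). Its genotype effects differed between the states by -1.40 (interaction adjusted p = 0.694).

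The level of CD3 genes in the libraries, their Xist level and their similarity also differed, in features chosen after their values were seen. The CD3 chains Cd3d, Cd3e and Cd3g, invariant parts of the T cell receptor complex, summed to 773 ± 39.3 CPM in steady-state WT, 98.4 ± 95.4 in steady-state KO, 953 ± 22.9 in infected WT and 138 ± 88.4 in infected KO libraries. The log2 difference of this sum between library means was -3.43 ± 1.21 at steady state and -2.96 ± 0.71 in infection. Values given relative to CD3 are list medians minus the mean log2 fold change of the 3 chains, whose SE is taken as the average of their 3 SEs. This mean was -2.77 ± 0.70 and -2.73 ± 0.69 for genotype at steady state and in infection. For infection in WT and KO cells it was 0.43 ± 0.64 and 0.46 ± 0.67. Values of genes per CD3 count use the summed counts instead, so the 2 scales are unlike. Within the KO groups the sum was 30.9 and 166 CPM at steady state and 75.2 and 200 in infection. Xist, the RNA that silences an X chromosome in female cells, was at 358 CPM in steady-state KO replicate 2 and 794 in infected KO replicate 2, and at 2.73 to 10.4 CPM in the other 6 libraries. High Xist in these 2 libraries points to female cells in them. The 46 Y-linked rows held 0 counts in every library, so male cells could not be sought and the sex behind the other 6 libraries stays unknown. Xist was high in replicate 2 of each KO group and in no WT library. A difference of sex may therefore add to the spread within KO groups and to the genotype differences. The ribosomal RNA precursor Rn45s took 7.52% and 9.0% of counts in steady-state WT, 5.78% and 0.536% in steady-state KO, 11.2% and 10.2% in infected WT, and 3.70% and 4.79% in infected KO libraries. Replicates were closer in WT than in KO groups. The chi-square per degree of freedom between replicate counts was 4.70 and 6.06 in WT and 31.5 and 45.5 in KO groups, at steady state and in infection.

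**Figure D1:**
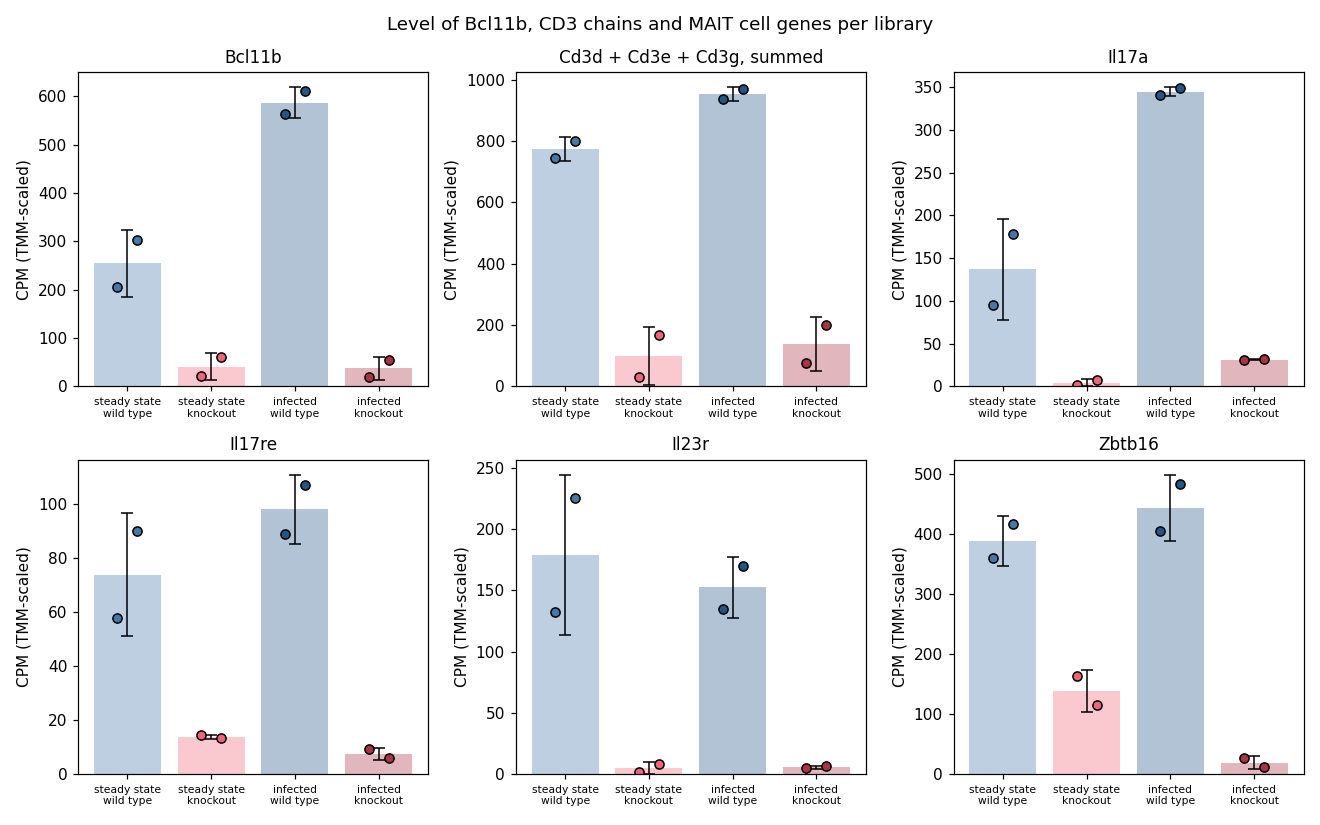
Bars give the mean and error bars the SD of TMM-scaled CPM in the 4 groups (n = 2), with each library as a dot, for Bcl11b, the sum of Cd3d, Cd3e and Cd3g, Il17a, Il17re, Il23r and Zbtb16. Bcl11b was at 254, 40.7, 587 and 37.1 CPM and the CD3 sum at 773, 98.4, 953 and 138 CPM in steady-state WT, steady-state KO, infected WT and infected KO libraries.

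Knockout and wild-type cells at steady state were compared to ask how the genotypes differed without infection. Of 23 genes of the type 17 programme, with which T cells make IL-17, 8 fell in KO cells. The list was lower by camera, though not with an estimated correlation (adjusted p = 0.553). Its median was 0.48 ± 0.79 (SE) relative to CD3, with 15 of 23 genes above 0. Il23r, a subunit of the IL-23 receptor (chromosome 6, 67422932 to 67491855), fell from 179 ± 65.5 to 4.95 ± 4.87 CPM (SD, n = 2; log2 fold change -4.89 ± 0.56, SE). Il17a, which encodes the cytokine IL-17A (chromosome 1, 20730905 to 20734496), fell from 137 ± 58.9 to 4.40 ± 4.09 CPM (-4.68 ± 0.53). Other large falls were the transcribed pseudogene Ptprv (-4.88), the potassium channel gene Kcnc1 (-4.88), Ly6g5b (-4.57), the Src family kinase gene Blk (-4.41), Ramp3, a partner of calcitonin family receptors (-4.09), and the metalloprotease gene Mmp25 (-3.94). Genes that rose included Hp, which encodes haptoglobin (35.3 ± 3.05 to 213 ± 72.6 CPM, 2.59 ± 0.35), Tnfaip6, which encodes a hyaluronan-binding protein (1.89), and Alas1, the first enzyme of haem synthesis (1.57). With edgeR 4 genes were higher and 55 lower, at adjusted p values from 0.0362 to 0.0490, against 443 higher and 665 lower with DESeq2. No gene passed without either steady-state WT replicate, either steady-state KO replicate or either infected WT replicate, whereas 339 were higher and 716 lower without infected KO replicate 1, and 349 and 704 without infected KO replicate 2. At an unadjusted p under 0.05, 1408 genes were higher and 1534 lower.

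In the type 17 list 19 genes were lower when adjusted over the list alone, and its median log2 fold change was -2.29. The 8 that fell included Serpinb1a, an inhibitor of neutrophil serine proteases (-2.61), Il17re, the receptor chain for IL-17C (-2.43), and Ramp1 (-2.18). Its camera adjusted p was 5.21e-14. Its genes were lower where the CD3 sum was lower too. Per CD3 count, a ratio for genes chosen after their values were seen, Il23r (-2.0 ± 0.42, SE), Il17a (-1.70 ± 0.59) and Ly6g5b (-2.23 ± 0.53) were still below 0 by more than 2 SE. Steady-state KO replicate 1 held only 41 CD3 counts, and a small offset was added to each gene's count. The SE was pooled over the 4 groups, so it can understate the error for genes with few counts in that library. Values within 2 SE of 0 were Kcnc1 (-1.65 ± 1.0), Ptprv (-1.41 ± 0.79), Blk (-1.05 ± 0.68), Il17rb (-0.49 ± 0.79), Itgae (-0.25 ± 0.59), Serpinb1a (0.85 ± 1.15), Il17re (1.07 ± 1.16), Ramp1 (1.24 ± 0.98), Il18r1 (1.59 ± 0.95), Gata3 (1.78 ± 0.90) and Zbtb16 (1.93 ± 1.40). Per count of 7 genes of the T cell receptor signalling list, Kcnc1 (-2.38 ± 0.91), Ptprv (-2.14 ± 0.63), Blk (-1.78 ± 0.50), Il17rb (-1.23 ± 0.61) and Itgae (-0.98 ± 0.44) were below 0 by more than 2 SE as well. The other genes stayed on their side of 2 SE. Among receptor genes Il17rb, part of the IL-25 receptor (-3.90), and Il18r1 (-1.84) fell, as did the type 2 transcription factor gene Gata3 (-1.64), the ectonucleotidase gene Nt5e (-1.46), the ERK phosphatase gene Dusp5 (-2.40) and Selplg, the P-selectin ligand (-2.62).

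Several other lists of T cell genes were lower by camera in steady-state KO cells. Relative to the CD3 chains the medians of all 31 lists lay above 0 in this comparison, since that scaling subtracts the same -2.77 from every list. The median was -1.44 for the 31 T cell receptor signalling genes, which turned to 1.47 relative to CD3 with the chains themselves left out (0 fell, 18 adjusted over the list alone; camera adjusted p = 1.02e-10, 0.684 as adjusted p with an estimated correlation). It was -1.49 for 17 innate-like T cell identity genes, 1.28 relative to CD3 (1 fell, 10 over the list alone; camera adjusted p = 8.62e-07; adjusted p = 0.684 with an estimated correlation). Cytokine receptor genes were at -0.78 with 4 of 38 lower, 1.99 relative to CD3 (15 lower and 1 higher over the list alone; adjusted p = 4.65e-08, 0.684 as adjusted p with an estimated correlation). Chemokine receptor and homing genes were at -1.09 with 1 of 26 lower, 1.67 relative to CD3 (9 over the list alone; adjusted p = 2.3e-05, 0.684 as adjusted p with an estimated correlation), and activation genes at -1.23 with 1 of 22 lower, 1.53 relative to CD3 (8 lower and 1 higher over the list alone; adjusted p = 3.67e-05, 0.692 as adjusted p with an estimated correlation). The 24 ribosomal protein genes, a quality list, had 0 falls over all genes and 24 adjusted over the list alone, at a median of -1.40 and of 1.37 relative to CD3 (adjusted p = 9.81e-15, 0.684 as adjusted p with an estimated correlation).

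Several smaller list changes at steady state depended on single libraries. Glycolysis genes were lower (median -0.78, 1.99 relative to CD3; 0 of 19 fell, 2 lower and 1 higher over the list alone; camera adjusted p = 0.00833; adjusted p = 0.762 with an estimated correlation). Also lower relative to all genes, and above 0 relative to CD3, were type 1 and cytotoxic genes (-0.73, adjusted p = 0.0238; 0 of 22 fell), type 2 genes (-1.18, 0.0246; 2 of 8 fell), inhibitory receptors (-0.69, 0.0287; 1 of 14 fell), cytokines (-0.86, or -0.59 with genes near 0 counts at their bound; 0.0198; 1 of 26 fell) and oxidative phosphorylation (-0.26, 0.0202; 0 of 26 fell). Their adjusted p with an estimated correlation was 0.684 to 0.762. Adjusted over the list alone 0, 4, 4, 8 and 0 of them were lower and 2 cytokines were higher. Lipid uptake and sterol genes were higher (median 0.46; 1 of 20 rose; adjusted p = 0.0238; adjusted p = 0.684 with an estimated correlation). Leaving out steady-state WT replicate 1 ended the calls of the cytokine (adjusted p = 0.0992), inhibitory (0.130), type 1 (0.594) and type 2 lists (0.0954). Without steady-state KO replicate 1 the type 1 (0.286) and oxidative phosphorylation lists (0.0882) were lost, without steady-state KO replicate 2 the cytokine list (0.0819), and the type 2 list also without infected WT replicate 2 (0.0753), infected KO replicate 1 (0.0571) or infected KO replicate 2 (0.0571). The type 2 call was also lost with no low count filter (0.085), and the type 2 (0.0658) and cytokine calls (0.139) without both libraries with high Xist. The interferon-stimulated (median 0.10, adjusted p = 0.615), cell cycle (median 0.31, mean 0.16, test lower, 0.644) and naive lists (median 0.13, mean -0.22, test lower, 0.540) did not pass. Tissue repair genes had a median of 0.09 and a mean of -0.42. The dissociation and stress list did not pass either, at a median of -0.06. Its heat shock gene Hspa1a, chosen after its values were seen, was at 634 and 358 CPM in WT and 1403 and 2892 in KO libraries. In infection it was at 627 and 136 CPM in WT and 1526 and 385 in KO libraries.

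Markers of other cells moved as well at steady state. Lung epithelium markers had a median of 1.18 in KO against WT cells (12 of 12 above 0, 0 passed; camera adjusted p = 0.0238; adjusted p = 0.762 with an estimated correlation) and neutrophil markers a median of 0.60 (0 of 9 passed; 0.0334; adjusted p = 0.684 with an estimated correlation). B and plasma cell markers were lower at -1.56, but at 1.20 relative to CD3 (0 of 9 passed; adjusted p = 0.0334; adjusted p = 0.740 with an estimated correlation). Macrophage markers were above 0 in 17 of 19 genes (median 0.55, adjusted p = 0.084). The epithelial call was lost without steady-state KO replicate 1 (adjusted p = 0.400) or steady-state WT replicate 2 (0.143), and the B cell call without steady-state WT replicate 2 (0.176) or steady-state KO replicate 2 (0.162). The neutrophil call was lost without steady-state WT replicate 2 (0.194), steady-state KO replicate 1 (0.125), infected KO replicate 1 (0.0571) or infected KO replicate 2 (0.0571), and with no low count filter (0.187) or the stricter one (0.078). Without both libraries with high Xist the B cell call was lost (0.226).

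The same genotypes were compared in Salmonella infection. In KO cells 14 of 23 type 17 genes and 6 of 17 innate-like T cell genes fell, and 23 of 31 interferon-stimulated genes, 8 of 9 neutrophil markers and 10 of 19 macrophage markers rose. These 5 lists passed by camera with the preset correlation and none did with an estimated one (adjusted p = 0.368 to 0.724). Relative to CD3 the type 17 median was -0.10 ± 0.83 and the innate-like one 1.18 ± 0.97 (SE). Il17a fell from 345 ± 5.63 to 31.3 ± 0.221 CPM (SD, n = 2; log2 fold change -3.46 ± 0.46, SE) and Zbtb16, which encodes the innate-like T cell factor PLZF, from 444 ± 55.0 to 18.9 ± 10.8 CPM (-4.53 ± 0.45). S100a8, which encodes a calprotectin subunit abundant in neutrophils, rose from 1.52 ± 0.533 to 152 ± 39.8 CPM (6.64 ± 0.55). Among the 8 largest rises, Tarm1 was at least 37.6-fold, Mrgpra2b at least 26.2-fold and Mrgpra2a at least 20.9-fold higher, against 0 counts in WT. With 1 to 3 counts in WT, the ratio was 248 (95% counting interval 44.3 to 9807) for Il1f9, an IL-36 cytokine gene, 134 (23.9 to 5328) for Ms4a4a, 104 (28.6 to 860) for Asprv1 and 87.9 (29.9 to 427) for the neutrophil chemokine receptor gene Cxcr2. The largest falls were Fam83a (ratio 132, 35.7 to 1099, by WT over KO), Kcnc1 (-6.40), the noncoding RNA Miat (ratio 43.9, 14.4 to 219), Ptprv (-5.31), Blk (-5.25), the water channel gene Aqp3 (-5.20), Il17rb (-5.17) and Ly6g5b (-5.09). With edgeR 1086 genes were higher and 697 lower, against 1552 and 1038 with DESeq2 and 828 and 873 with limma-voom. The counts were 437 higher and 329 lower without steady-state WT replicate 1, 438 and 327 without steady-state WT replicate 2, 10 and 24 without infected WT replicate 1, 0 and 0 without infected WT replicate 2, and 903 and 319 without infected KO replicate 1. Without infected KO replicate 2, 1587 were higher and 1111 lower.

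In infection 14 of the 23 type 17 genes fell and 16 were lower adjusted over the list alone, at a median of -2.83 and of -0.10 relative to the CD3 chains. The list was lower by camera (adjusted p = 5.15e-11; adjusted p = 0.398 with an estimated correlation). Il23r (-4.78), Il17re (-3.67), Ramp1 (-3.44) and Serpinb1a (-2.83) were among them. Among innate-like identity genes 6 of 17 fell and Plac8 rose (3.26), at a median of -1.56 that turned to 1.18 relative to CD3 (9 lower and 2 higher over the list alone; camera adjusted p = 0.000675; adjusted p = 0.724 with an estimated correlation). Of 31 T cell receptor signalling genes 12 fell, such as the adaptor gene Lat (-3.13) and Plcg1 (-1.25), at a median of -1.45 and of 1.47 relative to CD3 (17 lower and 1 higher over the list alone; adjusted p = 1.51e-07, 0.724 as adjusted p with an estimated correlation). Per CD3 count, for genes chosen after their values were seen, Il23r (-1.80 ± 0.42, SE), Kcnc1 (-3.57 ± 1.0), Blk (-2.38 ± 0.68), Il17rb (-2.13 ± 0.79), Itgae (-1.70 ± 0.59), Ptprv (-2.46 ± 0.79) and Ly6g5b (-2.10 ± 0.53) were below 0 by more than 2 SE. Values within 2 SE of 0 were Zbtb16 (-1.71 ± 1.40), Il17re (-0.75 ± 1.16), Il17a (-0.50 ± 0.59), Ramp1 (-0.49 ± 0.98), Serpinb1a (0.14 ± 1.15), Gata3 (0.43 ± 0.90) and Il18r1 (0.81 ± 0.95). Per signalling gene count each of these 14 genes stayed on its side of 2 SE, and Serpinb1a was at -0.19 ± 0.98. Cell cycle genes were lower, at a median of -1.29 and of 1.44 relative to CD3, with 3 of 30 past the threshold and 5 over the list alone, among them the replication genes Mcm2 (-1.78), Mcm7 (-1.35) and Rrm1 (-1.15) (adjusted p = 1.03e-07, 0.724 as adjusted p with an estimated correlation).

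Of 31 interferon-stimulated genes 23 rose in infected KO against infected WT cells and 29 were higher adjusted over the list alone, with a median of 2.04. They included the antiviral genes Oas1a (2.76) and Oasl2 (2.55), Gbp2, a guanylate-binding protein gene (309 ± 105 to 1474 ± 418 CPM, SD, n = 2; 2.25 ± 0.38, SE), and Rtp4 (1.79). The list passed by camera (adjusted p = 5.15e-11; adjusted p = 0.724 with an estimated correlation). Neutrophil markers rose in 8 of 9 genes (8 over the list alone), with a median of 5.19, or 5.18 with genes near 0 counts at their bound (adjusted p = 2.37e-08; 0.368 as adjusted p with an estimated correlation). Macrophage and monocyte markers rose in 10 of 19 genes (18 over the list alone; median 2.75), among them the Fc receptor gene Fcgr3 (3.21), Lyz1 (3.12), Chil3 (3.02) and Mpeg1 (2.81) (adjusted p = 1.88e-07, 0.724 as adjusted p with an estimated correlation). Dendritic cell markers rose in 4 of 10 genes, such as Itgax (2.57) and the MHC class II gene H2-Aa (2.77), with 6 higher and 1 lower over the list alone (median 2.40, adjusted p = 0.00808, 0.724 as adjusted p with an estimated correlation). Endothelium and fibroblast markers rose in 5 of 12, such as Col3a1 (2.66) and Mgp (2.13), with 5 over the list alone (median 1.71, adjusted p = 0.00209, 0.724 as adjusted p with an estimated correlation).

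Further lists moved both ways in infection. Cytokine receptor genes had 4 rises, such as the decoy receptor gene Il1r2 (4.31), and 10 falls among 38, at a median of -0.48 and of 2.26 relative to CD3 (6 higher and 14 lower over the list alone; adjusted p = 0.0183, 0.765 as adjusted p with an estimated correlation). Activation genes had 1 rise, Irf8 (2.21), and 5 falls among 22, such as Irf4 (-3.27), Nr4a3 (-2.49) and Dusp5 (-1.72), at a median of -0.35 and of 2.38 relative to CD3 (2 higher and 5 lower over the list alone; adjusted p = 0.0241, 0.765 as adjusted p with an estimated correlation). Ribosomal protein genes were lower with 0 of 24 past either threshold, at a median of -0.52 and of 2.22 relative to CD3 (adjusted p = 0.000209, 0.765 as adjusted p with an estimated correlation). All 3 calls were lost without infected KO replicate 1, at adjusted p values of 0.232, 0.595 and 0.116. Lists that did not pass still held changed genes. Inhibitory receptor genes had 1 rise and 4 falls, including Pdcd1 (-3.37), Cd96 (-2.97) and Tox (-2.86), and naive and memory genes had 3 rises, including Actn1 (1.70), and 1 fall, Foxo1 (-1.47). NK receptor and adaptor genes had 4 rises, including Tyrobp (3.14) and Fcer1g (3.70), which myeloid cells also express. Glycolysis genes had 4 rises, including the glucose transporter gene Slc2a1 (2.19), and 1 fall, Slc2a3 (-1.86). Cytokine genes had 5 rises, such as Il6 (3.26), and 5 falls, such as Cd40lg (-3.81), at a median of 0.37 with the test towards lower. Among the markers of regulatory T cells Ikzf2 (-2.48) and Il2ra (-2.27) fell, at a median of 0.48 and a mean of -0.20.

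Infected and steady-state WT libraries were compared to ask how they differed with Salmonella infection. Both groups also held epithelial and stromal markers, so changes cannot be ascribed to MAIT cells alone. Gbp6, an interferon-inducible GTPase gene, increased from 66.5 ± 10.4 to 697 ± 78.7 CPM (SD, n = 2; log2 fold change 3.39 ± 0.28, SE, adjusted p = 0.0304), Apol7b from 12.4 ± 1.43 to 135 ± 28.3 CPM (3.44 ± 0.33, adjusted p = 0.0383) and the GTPase gene Igtp from 52.1 ± 6.89 to 380 ± 97.8 CPM (2.86 ± 0.28, adjusted p = 0.0383). These 3 genes passed with edgeR and 0 fell, while 923 were higher and 1428 lower at an unadjusted p under 0.05. DESeq2 called 263 higher and 421 lower, and limma-voom 3 and 0. No gene passed without either steady-state WT replicate or either infected WT replicate, and the counts were 6 and 2 without steady-state KO replicate 1, 6 and 1 without steady-state KO replicate 2, 149 and 228 without infected KO replicate 1, and 139 and 222 without infected KO replicate 2.

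By list, cell cycle genes were higher in infected WT cells, with a median of 1.89, 0 of 30 past the threshold over all genes and 27 adjusted over the list alone (camera adjusted p = 4.86e-17; adjusted p = 0.912 with an estimated correlation). Cdk1, a mitotic kinase gene, was at 3.62 ± 1.91 and 36.0 ± 7.96 CPM (3.27, adjusted p = 0.087), and Ccna2 differed by 2.77. Interferon-stimulated genes were higher with 1 of 31 past the threshold and 10 over the list alone, at a median of 0.96 (adjusted p = 4.47e-11; 0.912 as adjusted p with an estimated correlation). Oxidative phosphorylation genes were higher (median 0.39, but -0.04 relative to CD3; 0 of 26 by either count; adjusted p = 0.000271; 0.934 as adjusted p with an estimated correlation). Naive and memory genes were lower (median -1.11; 0 of 15, 4 over the list alone; adjusted p = 0.000376; 0.590 as adjusted p with an estimated correlation). Markers of neutrophils (median -2.66, or -1.79 with genes near 0 counts at their bound; 7 of 9 over the list alone; adjusted p = 0.000964; 0.806 as adjusted p with an estimated correlation), of endothelium and fibroblasts (-1.25; 6 of 12; 0.000271; 0.934 likewise) and of B cells (-1.38; 0 of 9; 0.0261; 0.934 likewise) were lower, with 0 past the threshold over all genes. The B cell call was lost without steady-state WT replicate 2 (adjusted p = 0.105). Type 17 genes did not pass (median 0.30, and -0.14 relative to CD3; adjusted p = 0.103). Median and mean lay on opposite sides of 0 for chemokine receptors (0.26, -0.05), apoptosis (0.14, -0.03), lipid uptake (0.12, -0.18), macrophages (0.25, -0.37), dendritic cells (0.24, -0.23) and regulatory T cells (-0.10, 0.11), of which none passed by camera at this threshold. The CD3 sum differed by 0.30 ± 0.06 between the libraries of these groups.

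Infected and steady-state KO libraries were compared in the same way. Macrophage markers summed to 3814 ± 2348 CPM at steady state and 13299 ± 6136 in infection (SD, n = 2), and dendritic cell markers to 1543 ± 1064 and 9791 ± 5081. The changes below therefore cannot be ascribed to MAIT cells alone. H2-M2, an MHC class I gene, was at least 63.7-fold higher, against 0 counts at steady state. Saa3, an acute phase serum amyloid gene, rose from 3.79 ± 3.17 to 1117 ± 1154 CPM (SD, n = 2; log2 fold change 8.55 ± 1.29, SE) and the chemokine gene Cxcl9 by 7.33. The ratio was 318 (95% counting interval 56.9 to 12590) for Ido1, an enzyme of tryptophan breakdown, and 230 (41.0 to 9092) for the chemokine gene Cxcl5, with Inhba (5.82), Fam26f (5.77) and Slamf8 (5.72) next. Nr1d1, which encodes the clock repressor REV-ERB alpha, fell from 167 ± 20.5 to 3.59 ± 2.37 CPM (-5.45 ± 0.48), and Dbp, a clock output transcription factor gene, fell too (-4.28). Other falls were the macrophage scavenger receptor gene Cd163 (-5.14), Colq (-4.89), the sodium channel gene Scn3a (-4.27), Nkain1 (-4.16), Abca6 (-4.06), Fam205a2 (-3.41) and Zbtb16 (-2.85). Il17a was at 4.40 ± 4.09 and 31.3 ± 0.221 CPM (2.55, adjusted p = 0.057). With edgeR 188 genes were higher and 39 lower, against 717 and 408 with DESeq2. No gene passed without either steady-state WT replicate, and the counts were 75 and 83 without steady-state KO replicate 1, 1 and 0 without steady-state KO replicate 2, 73 and 12 without infected WT replicate 1, 49 and 6 without infected WT replicate 2, 1284 and 687 without infected KO replicate 1, and 78 and 6 without infected KO replicate 2. Without steady-state KO replicate 2 and infected KO replicate 2, the libraries with high Xist, 106 were higher and 16 lower, and 82 of the 227 calls were shared.

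Interferon-stimulated genes rose in 23 of 31 members in infected KO cells and 31 adjusted over the list alone, at a median of 3.0, including Gbp2 (4.06), Gbp4 (3.79) and Igtp (3.77) (camera adjusted p = 1.94e-27; adjusted p = 0.519 with an estimated correlation). Neutrophil markers rose in 2 of 9, S100a8 (3.52) and S100a9 (2.79), with 8 over the list alone (median 2.71, adjusted p = 2.84e-07; 0.471 as adjusted p with an estimated correlation). Ribosomal protein genes were higher (median 1.18; 0 of 24, 23 over the list alone; adjusted p = 1.31e-10; 0.641 as adjusted p with an estimated correlation), as were glycolysis (1.59; 0 of 19, 14 over the list alone; 1.7e-06; 0.641 likewise) and oxidative phosphorylation genes (0.69; 0 of 26, 3 over the list alone; 2.3e-05; 0.641 likewise). Macrophage markers had a median of 2.0 (1 of 19 rose, Fcgr3 by 3.06; 11 higher and 1 lower over the list alone; adjusted p = 0.000545; 0.641 as adjusted p with an estimated correlation). In all 20 lists were higher by camera, and the T cell receptor list (median 0.35, 0 of 31; adjusted p = 0.0254; adjusted p = 0.762 with an estimated correlation) was at -0.13 ± 0.69 (SE) relative to CD3, a scaling that subtracts the same 0.46 from every list. Its call was lost without steady-state KO replicate 1 (0.375) and without infected KO replicate 2 (0.810), in both cases towards lower. Without both libraries with high Xist the macrophage call was lost (adjusted p = 0.180).

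The other 13 lists that were higher in infected KO cells had an adjusted p of 0.641 to 0.669 with an estimated correlation. Type 1 genes (0.88), cytokines (1.23), dendritic cell markers (1.69), NK receptors (0.75), apoptosis (0.57), cytokine receptors (0.58), chemokine receptors (0.61), activation (0.93), cell cycle (0.51), inhibitory receptors (0.62), tissue repair (0.74), innate-like identity (0.59) and B cell markers (1.59) had camera adjusted p values from 0.000747 to 0.0355. At most 3 genes of each rose over all genes and at most 9 adjusted over the list alone. They included Irf8 (2.47), Il1r2 (2.81), Socs1 (2.02), Bak1 (1.80), Tyrobp (2.69), Osm (2.99) and H2-Ab1 (3.10). Without steady-state KO replicate 1 the calls of the cell cycle (adjusted p = 0.521), chemokine receptor (0.207), cytokine receptor (0.0932), inhibitory (0.177), innate-like (0.521), NK receptor (0.0533) and type 1 lists (0.0932) ended. Without infected KO replicate 2 those of apoptosis (0.052), cell cycle (0.411), chemokine receptors (0.184), cytokine receptors (0.0698), inhibitory receptors (0.498), innate-like identity (0.522), B cells (0.522), activation (0.396), tissue repair (0.0797) and type 1 (0.0699) ended, and without steady-state KO replicate 2 those of B cells (0.152), dendritic cells (0.152) and tissue repair (0.235). Without both libraries with high Xist those of dendritic cells (0.143), cytokines (0.180), apoptosis (0.268), activation (0.730), tissue repair (0.614) and B cells (0.842, towards lower) ended. The stricter filter also ended that of B cells (0.109). Median, mean or test differed in sign for type 17 genes (-0.13, mean 0.10, adjusted p = 0.612), mast cells (-0.04, 0.11), erythroid cells (0.08, -0.01), regulatory T cells (0.04, 0.20) and dissociation genes (0.04, -0.04), of which none passed.

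Whether the genotype effect differed between the states was tested with the interaction. No gene passed with edgeR (0 of 13405, smallest adjusted p = 0.391), 1141 had an unadjusted p under 0.05 (818 higher and 323 lower), and DESeq2 called 123 and limma-voom 0. Without infected KO replicate 1, 200 genes passed. The smallest p values belonged to S100a8 (6.18 ± 0.72, SE), S100a9 (5.62 ± 0.70) and Il1r2 (4.40 ± 0.62). By camera 17 lists differed, and none did with an estimated correlation (adjusted p = 0.190 to 0.715). The genotype effect was higher in infection for interferon-stimulated genes (median 1.61, adjusted p = 1.46e-15) and neutrophil markers (4.88, 8.51e-12) and lower for cell cycle genes (-1.38, 1.18e-09). For the type 17 list the difference between states was -0.23 and did not pass (adjusted p = 0.327).

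The genotype effects of both states, which share no library, were compared last. Of the genes called, 52 were called in both in the same direction, 4 higher (0.324 for independent lists) and 48 lower (2.86 for independent lists), and 0 in opposite directions. With DESeq2 1 gene and with no low count filter 37 genes were called in opposite directions. The CD3 chains fell alike in both states (-2.77 and -2.73). A shared change in the mixture of cells would also give such an overlap, which the comparison with independent lists cannot tell apart. Across 13405 genes, which are not independent replicates, the log2 fold changes had r = 0.605 and rho = 0.659 and 75.2% had the same sign. The correlation r was lower, at 0.374, without infected KO replicate 1. It was 0.391 without steady-state KO replicate 1 and 0.259 with no low count filter. The 10 named by the rule were Ptprv, Kcnc1, Il23r, Ly6g5b, Blk, Il17rb, Lingo4 (-3.57 at steady state), Ramp3, Apol7b (-3.52 at steady state) and Il17a, which all fell in both states. The overlap was 0 without either steady-state WT replicate, either steady-state KO replicate or either infected WT replicate, 272 without infected KO replicate 1 and 771 without infected KO replicate 2.

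**Figure D2:**
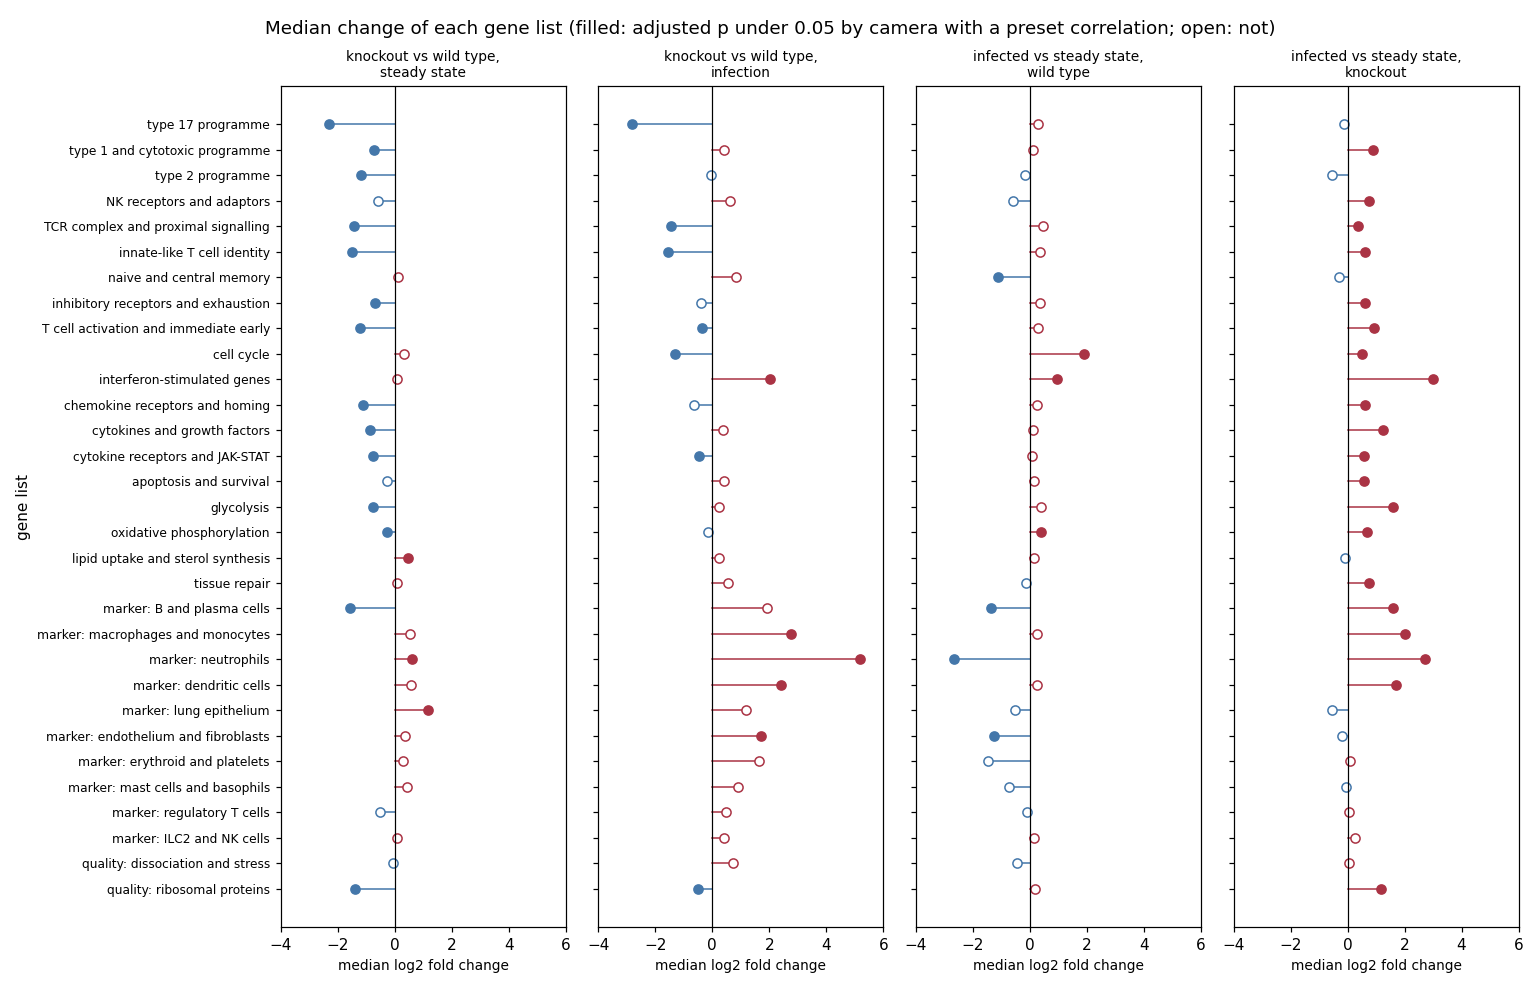
Median log2 fold change of the 31 lists in the 4 comparisons, filled where the camera adjusted p with the preset correlation was under 0.05. Of the lists, 17 were filled for genotype at steady state, 12 for genotype in infection, 7 for infection in WT and 20 for infection in KO cells; relative to the CD3 chains the medians of 31, 30, 3 and 19 lists were above 0.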

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

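The tests of the marker pattern weighed here were chosen after the result was seen, and the interaction tests of the lists were planned. The genotype effect differed between infection and steady state in 17 lists by the camera test of the interaction with the preset correlation, and in 0 of them with an estimated correlation (adjusted p = 0.190 to 0.715), so each rests on the preset correlation. Each value is the median log2 difference, the effect in infection minus that at steady state.

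The difference was 1.61 for interferon-stimulated genes, 4.88 for neutrophil markers and -1.38 for cell cycle genes, and leaving out any 1 library ended none of these 3 calls. It was 2.17 for macrophage and monocyte markers, 3.15 for B and plasma cell markers, 0.90 for ribosomal protein genes, 1.83 for dendritic cell markers and 0.77 for naive and memory genes. Without steady-state KO replicate 2 and infected KO replicate 2 together, the libraries with high Xist, the macrophage (adjusted p = 0.132), B cell (0.0537), ribosomal (0.456), apoptosis (0.522), cytokine (0.209), glycolysis (0.0966), tissue repair (0.444) and cytokine receptor calls (0.0537) were lost. It was 1.21 for glycolysis, lost without infected KO replicate 2 (adjusted p = 0.165), and 1.39 for NK receptors, lost without steady-state WT replicate 1 (0.0506). It was 0.66 for apoptosis genes and 1.01 for cytokines, both lost without infected KO replicate 2 (adjusted p = 0.299), the cytokines also without infected WT replicate 2 (0.148).

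The difference was 0.87 for endothelium and fibroblast markers, lost without infected KO replicate 1 (adjusted p = 0.147), infected WT replicate 2 (0.0905) or steady-state KO replicate 2 (0.307). It was 0.84 for tissue repair genes, lost without infected KO replicate 2 (adjusted p = 0.125), infected WT replicate 2 (0.0905) or steady-state KO replicate 2 (0.111). For type 1 genes it was 0.77, lost without infected KO replicate 2 (adjusted p = 0.543), infected WT replicate 2 (0.0905), steady-state KO replicate 1 (0.541) or steady-state WT replicate 1 (0.400). For chemokine receptors it was 0.52, lost without infected KO replicate 2 (adjusted p = 0.571), infected WT replicate 1 (0.0709), steady-state KO replicate 1 (0.541) or steady-state WT replicate 1 (0.0734). For cytokine receptors it was 0.48, lost without infected KO replicate 2 (adjusted p = 0.543), infected WT replicate 1 (0.0549) or steady-state KO replicate 1 (0.367).

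Markers of macrophages, neutrophils, epithelium and stroma had medians above 0 in KO against WT libraries of both states, except that the medians were -0.12 for macrophages and -0.39 for stroma in steady-state KO replicate 2. A sort for MAIT cells would remove such cells, yet WT libraries held their RNA as well. In steady-state WT libraries epithelial markers summed to 4439.5 ± 1387 CPM and stromal ones to 6354 ± 83.8 (SD, n = 2), against 773 ± 39.3 for CD3. All 12 of 12 genes of both lists reached 10 CPM in both of these libraries. A lower share of T cells as the whole cause would raise every other type alike. In infection the neutrophil median exceeded the epithelial one by 4.01 ± 0.67 (SE over genes) and by 3.41 ± 1.27 between the 2 infected KO libraries. It was 3.79 against 1.65 in infected KO replicate 1 and 4.80 against 0.12 in replicate 2, so the rises were unequal in both. The second SE rests on 2 values and leaves out the spread between WT libraries. Neutrophil markers summed to 21.3 and 33.8 CPM in infected WT and to 654 and 1020 in infected KO libraries. Epithelial markers summed to 2598 and 2202 CPM in infected WT and to 7125 and 2297 in infected KO libraries. For these 2 lists in infection the values argue against a lower T cell share as the whole cause. The test does not say what else contributed. The highest and lowest of 4 lists were compared, S100a8 and S100a9 reached 152 and 148 CPM, and 0 of the 9 neutrophil markers belonged to another list or reached 10 CPM in both infected WT libraries. At steady state the epithelial median exceeded the stromal one by 0.80 ± 0.30 over genes but by 0.64 ± 0.54 between libraries, under a rule added after the first value was seen, so a lower T cell share cannot be told apart from unequal changes there. More neutrophil RNA in infected KO libraries may come from more of these cells in those lungs or in the sort, which stays open and untested.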

How the results depend on the processing

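The removal of Rn45s and of both libraries with high Xist and the scaling to T cell genes were chosen after the data were seen, and the other alternatives were planned. With 2 libraries per group and 4 residual degrees of freedom, counts of genes depended strongly on the method and on single libraries. Counts are higher then lower. Relative log expression factors, the stricter filter and the removal of Rn45s kept each count within 1.5 times the main one, and the median of all genes moved by at most 0.05 with DESeq2, relative log expression or limma-voom. The cause of the differences was not tested.

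For knockout against wild type at steady state (4 and 55) DESeq2 called 443 and 665 genes, limma-voom 7 and 91, no filter 1000 and 1069, only the 4 libraries 17 and 117, and the fit without both Xist-high libraries 585 and 1087. DESeq2, no filter and the last fit shared all 59 calls. For the infected comparison (1086 and 697) no filter called 2750 and 1198, only the 4 libraries 236 and 180, and the fit without both Xist-high libraries 2951 and 2480, with 1758 of 1783 calls shared. For infection in wild-type cells (3 and 0) DESeq2 called 263 and 421, no filter 504 and 1161, only the 4 libraries 809 and 951, and the fit without both Xist-high libraries 776 and 916. For infection in knockout cells (188 and 39) DESeq2 called 717 and 408, limma-voom 61 lower, no filter 1255 and 855, only the 4 libraries 0 and 0 with edgeR (1008 and 669 at an unadjusted p under 0.05 in that fit), and the fit without both Xist-high libraries 106 and 16, with 82 of 227 calls shared. The interaction (0) had 123 calls with DESeq2 and 715 with no filter. The overlap of the genotype effects (52) was 701 with DESeq2, 1346 with no filter and 1500 without both Xist-high libraries.

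The replicate number as a block gave 106 and 492 genes at steady state, 1630 and 1118 in infection, 24 and 48 for infection in wild-type cells and 256 and 72 in knockout cells, and an overlap of 448. The groups share only these numbers. Same-numbered libraries deviated together with correlations of 0.03 to 0.25 across genes, the labels do not say what a number marks, and with 2 pairs this is no evidence of pairing. With the replicate block Bcl11b at steady state was -2.72 (adjusted p = 0.0267, over a range of 6.47e-12 to 0.401 for the alternatives).

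Leaving out 1 library at a time gave 0 to 349 genes higher and 0 to 716 lower for genotype at steady state, 0 to 1587 and 0 to 1111 in infection, 0 to 149 and 0 to 228 for infection in wild-type cells, 0 to 1284 and 0 to 687 in knockout cells, 0 to 200 for the interaction and 0 to 771 for the overlap. Libraries left out with the highest counts were infected KO replicates 1 and 2. The remaining partner was assumed to vary like the other groups.

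Bcl11b kept its direction in both genotype comparisons under each alternative except scaling to T cell genes. It turned to 0.64 ± 0.37 per CD3 count and was at -0.09 ± 0.22 per signalling gene count at steady state. At steady state it passed with DESeq2 (-2.58), no filter (-2.68), the replicate block (-2.72), without both Xist-high libraries (-3.60) and without infected KO replicate 1 (-2.58) or 2 (-2.58), and single libraries left out gave -3.50 to -2.08. In infection they gave -4.90 to -3.43, and the call was lost without either infected WT replicate.

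Of the lists, 2 turned in the comparison of infected with steady-state KO cells. B and plasma cell markers (camera adjusted p = 0.0355) turned to lower without both Xist-high libraries (0.842) and lost their call with the stricter filter (0.109). T cell receptor genes (0.0254) turned to lower without steady-state KO replicate 1 (0.375) or infected KO replicate 2 (0.810). With fry, which asks whether a list moves to one side and not whether it differs from other genes, 15 list calls were lost for genotype at steady state, 10 in infection, 7 for infection in wild-type cells, 18 in knockout cells and 16 for the interaction. It kept type 17 genes in both states (adjusted p = 0.0172 and 0.0104) and type 2 genes at steady state (0.0172). It also kept neutrophil markers for genotype in infection (0.00205), infection in knockout cells (0.016) and the interaction (0.0128), and interferon-stimulated genes for infection in knockout cells (0.016). It added type 2 genes, lower, for genotype in infection (0.0385). Depth limits low genes most in steady-state KO replicate 1, the shallowest library at 1256020 counts, where 3 counts correspond to 2.39 CPM.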

Other observations

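The tests of the type 17 and Bcl11b patterns were chosen after the results were seen, several versions were run, and the clock genes were chosen after their values were seen, while the prediction for the opposite clock genes was written before. Genes that no list holds are described first. As Nr1d1 and Dbp were among the largest falls in infected against steady-state KO cells, 10 clock output genes were looked up, a set that no list or set test covers. Of these, 5 fell, Nr1d1 (-5.45), Nr1d2 (-2.67), Dbp (-4.28), Tef (-1.70) and Hlf (-2.35), while Per1 (-1.08), Per2 (-0.55), Per3 (-1.40), Ciart (-1.05) and Bhlhe41 (0.43) did not pass. In WT cells 10 of 10 were below 0, at -3.27 to -0.12, and 0 passed by edgeR. Between knockout and wild-type cells 0 of the 10 passed at steady state and 4 in infection, Nr1d1 (-3.76), Hlf (-2.87), Nr1d2 (-1.83) and Per2 (2.21), as did Arntl (-1.33) and Cry1 (-0.85) of the opposite phase. At steady state the mean of the opposite-phase genes Arntl, Npas2, Clock and Cry1 was -0.94 ± 0.34 (SE over 4 genes) in KO against WT cells. Of these, 1 was above 0 and 0 passed.

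Another time of day at harvest of the infected animals may account for the 5 falls in infected KO cells. A shift in clock phase would raise Arntl, Npas2, Clock and Cry1, which peak in the opposite phase. Their mean was 0.45 ± 0.30 (SE over 4 genes) in infected against steady-state KO cells, with 3 of 4 above 0 and 0 passed, and in WT cells it was -0.06 ± 0.30. With Nfil3 (1.75, adjusted p = 0.0563), an opposite-phase gene that the prediction did not name, it was 0.71 ± 0.35 in KO cells, 2.05 SE above 0, and -0.11 ± 0.24 in WT cells, so the choice of genes decides and a shift cannot be told apart from a loss of clock output with infection. At steady state the mean with Nfil3 was -1.12 ± 0.32 in KO against WT cells, so the rise in infected KO cells started from a lower level. A difference in harvest time between the steady-state genotypes was not tested. The mixture of cells also differed between the KO groups, with macrophage markers at 3814 ± 2348 CPM at steady state and 13299 ± 6136 in infection (SD, n = 2). The falls of clock genes therefore cannot be ascribed to MAIT cells alone. Times of harvest were not given in the sources used here, and an effect of infection on the clock stays open.

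Lower Bcl11b and type 17 genes in KO libraries might reflect a lower share of T cells, as the CD3 sum fell as well. Per CD3 count Bcl11b differed by 0.64 ± 0.37 at steady state (0.65 ± 1.06 from a fit with CD3 counts as library size), as a lower share would give, and by -1.20 ± 0.37 in infection (-1.20 ± 1.05 from that fit, where the median SE of all genes was 1.18). Since CD3 genes could themselves respond to the knockout, 7 signalling genes served as a second reference, per which Bcl11b differed by -0.09 ± 0.22 and -1.53 ± 0.22. By the ratios of libraries, both references argue against a lower share as the whole cause of lower Bcl11b in infected KO than in infected WT libraries. That contrast rests on a higher ratio per CD3 count in infected WT (0.602 and 0.629) than in steady-state WT libraries (0.276 and 0.378). Infected KO libraries (0.263 and 0.272) lay near the latter. The fit with CD3 counts as library size lay within 2 SE of 0 there and cannot decide. The signalling genes are T cell genes too and could also respond to the knockout. The type 17 median minus the CD3 chains was 0.48 ± 0.79 at steady state and -0.10 ± 0.83 in infection (1.39 ± 1.31 and 0.31 ± 0.85 from that fit, 0.06 ± 0.73 and -0.28 ± 0.78 by the signalling genes), too wide to decide. Reading Bcl11b by the spread of its own ratios between libraries was also chosen after the values were seen, and an effect of Bcl11b on type 17 genes within T cells stays open.

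Bcl11b counts per CD3 count were 0.276 and 0.378 in steady-state WT, 0.683 and 0.364 in steady-state KO, 0.602 and 0.629 in infected WT, and 0.263 and 0.272 in infected KO libraries. The surfactant gene Sftpc was at 2008 ± 581 CPM (SD, n = 2) in steady-state WT, 2243 ± 2726 in steady-state KO, 830 ± 125 in infected WT and 1348 ± 811 in infected KO libraries. The lysozyme gene Lyz2 was at 1165 ± 275, 1270 ± 1047, 938 ± 156 and 4608 ± 1505 CPM in the same order. Both were chosen after their values were seen.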
